A study of Mus musculus with 16 samples.

How the data were processed

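Libraries were made from genomic DNA of E14TG2a mouse embryonic stem cells with wild-type Dnmt1 or the heterozygous N1580A knock-in, per the labels' protocols. Cells received 1 mM Ado-6-azide by electroporation and genomic DNA was isolated 3 h later. Per the labels' protocols, 900 ng of sonicated DNA was ligated to adapters, azide-bearing DNA was joined to a biotinylated oligonucleotide by copper-catalysed cycloaddition, and enriched DNA was primed from that oligonucleotide, amplified and sequenced on an Ion Proton. Per the submitters' processing notes, the tools were cutadapt 4.4, BWA 0.7.17-r1188 and SAMtools 1.12, with genome build mm10. Parameters, strand handling, the distance allowed between a read start and its CpG and any filter on duplicates are not given in the sources used here.

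The authors deposited 1 table per library with chromosome, position and coverage. Per the file headers and values, the deposited coverage is a whole-number count of reads per listed position, of at least 1, with no normalization, on 20 or 21 chromosomes per library. Each position appeared once per table and positions lay at least 2 bases apart. Unlisted positions were taken as a count of 0. Reads carry no molecular identifiers, so reads at 1 position can be PCR copies, and intervals and floors cover counting error only. Mean reads per position were 11.4 on day 0 and 4.08 on day 8. The number of distinct positions was therefore used beside the reads throughout.

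Gene bodies came from the RefSeq annotation of GRCm38.p6, whose chromosomes have the coordinates of mm10. It gave start, end and type for 21887 protein-coding and 12727 lncRNA genes, without strand, exons or sequence. The promoter test planned before the data were examined was therefore replaced by counts within 1 kb of either annotated gene end. Exons, introns, CpG islands and repeats were not used here, and shares were set against bases, not reference CpGs. Counts were summed from the first to the last base of each gene. Of the genes, 37.7% overlap another, and a read in several genes counted for each, so overlapping and antisense genes are not told apart, nor are reads of near-identical copies. Collapsed repeats can draw reads from many copies to 1 place.

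Groups and replicate numbers came from the sample titles. Totals and positions were compared by two-sided exact permutation tests of mean log10 values, and trends over days by exact permutation of Pearson and Spearman correlations, using Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene counts were fitted with edgeR 4.0.16 (R 4.3.3) over the 8 day libraries, with filterByExpr, TMM scaling, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 change divided by the square root of the F statistic. Other settings were refitted with edgeR, and DESeq2 1.42.0 was run as another tool. The common biological coefficient of variation was 0.488 for reads and 0.00988 for distinct positions. TMM factors lay between 0.981 and 1.02. The median log2 change over all genes was 0.18 on day 8 with TMM and 0.23 with library totals. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, which does not compare a list with other genes. On day 8 fry passed 14 of 19 lists with reads and 3 of 18 with distinct positions; its adjusted p for the long cell adhesion genes was 0.00618 and 0.0617. They covered long adhesion genes, clustered protocadherins, naive and formative pluripotency, methylation machinery, imprinted, germline, 2-cell-like and Hox or Polycomb genes, markers of 5 other lineages, housekeeping, X-linked, olfactory, vomeronasal and zinc finger genes.

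Genes were named by a rule fixed before the data were examined. For day 8 it took the 8 largest changes each way among genes past the threshold, at or above the median log2 abundance of 3.74, with both day 8 libraries on one side of both day 0 libraries. It added up to 2 called members per list and 11 fixed genes, the 4 largest each way for days 2 and 4, and up to 5 each way near gene ends. Where both day 0 libraries had 0 positions, the fold was bounded against a floor of 3 positions over the 2 libraries, as shares of all positions listed, and fitted folds were not used. The count of the later day entered as it stood, so these bounds allow for counting error on day 0 only.

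On counts simulated for 29466 genes, the day 8 test on reads recovered 21% of genes changed 2-fold and 76% of those changed 4-fold, with 4 unchanged genes called. With distinct positions, simulated for 19562 genes, it recovered 37% and 87%, with 8 unchanged genes called. Near gene ends, simulated for 26850 genes, it recovered 0% of both. Changed genes were drawn from those at or above the median mean count. The dispersion was the trended one for reads and gene ends and the tagwise one for positions. Each gene had the same dispersion in all simulated libraries, so day 0 was as quiet as later days. Calls that unequal spread between days may cause are therefore not measured. Alternatives covered other normalizations, filters, DESeq2, distinct positions, CpGs in 1 gene only, thinning to 4202118 reads, a replicate block, fits of 4 libraries and leaving out each library.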

Results

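The study tracked where the maintenance DNA methyltransferase DNMT1 acts in mouse embryonic stem cells of the line E14TG2a. The tracked cells carry a heterozygous Dnmt1 knock-in, N1580A, whose product can use Ado-6-azide, an analog of the methyl donor S-adenosylmethionine. The azide group left on DNA was joined to a biotinylated oligonucleotide, and enriched fragments were sequenced from that oligonucleotide, so that a read marks a CpG at or near a labelled cytosine. Data came from 16 libraries in 7 groups. The heterozygous knock-in (Het) and wild-type Dnmt1 (WT) groups had 3 libraries each, and the wild-type control and days 0, 2, 4 and 8 of the shift out of the naive state had 2 each. Naive cells grew with 2 kinase inhibitors, and the inhibitors were withdrawn for the 8 days of priming. The labels give neither the culture state of the Het triplicate nor the difference between the WT and wild-type control groups. Read totals were 4202118 to 25175264 in the 11 Het and day libraries and 1640 to 22890 in the 5 wild-type libraries. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these libraries only, which may be technical. For distinct positions the fitted spread was close to counting error (common biological coefficient of variation 0.00988).

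The first comparison asked how much signal depended on the knock-in allele. Het libraries held 19127067, 25175264 and 21836296 reads, against 9503, 1640 and 19723 reads in WT libraries. The geometric mean was 3246-fold higher in Het, and the smallest Het library exceeded the largest WT library 970-fold. Listed CpG positions numbered 1641850 to 3423423 in Het and 960 to 5625 in WT, a geometric mean 893-fold higher. A two-sided exact permutation test gave p = 0.1 for both quantities, the smallest value that 3 against 3 libraries allow. Without WT replicate 2 or 3 the fold in reads was 1600 and 5549. Totals also depend on how much of each library was loaded on the sequencer, which the labels do not give.

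The wild-type control libraries held 22890 and 8179 reads at 9150 and 3501 positions. Every day library exceeded both of them, by at least 184-fold in reads and 42.6-fold in positions. Over all 8 day libraries, the geometric mean was 641-fold higher in reads and 239-fold higher in positions, with an exact permutation p = 0.0222 for each, the smallest value 8 against 2 can give. Without control replicate 1 the fold in reads was 1072, and without control replicate 2 it was 383, with the exact p at 0.111, its smallest value there. Day by day, reads exceeded the control 331-fold on day 0, 692-fold on day 2, 876-fold on day 4 and 842-fold on day 8, each with an exact p = 0.333, the smallest value 2 against 2 can give. Without control replicate 1 or 2 these folds were 553 and 198, 1158 and 414, 1466 and 524, and 1408 and 503.

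**Figure D1:**
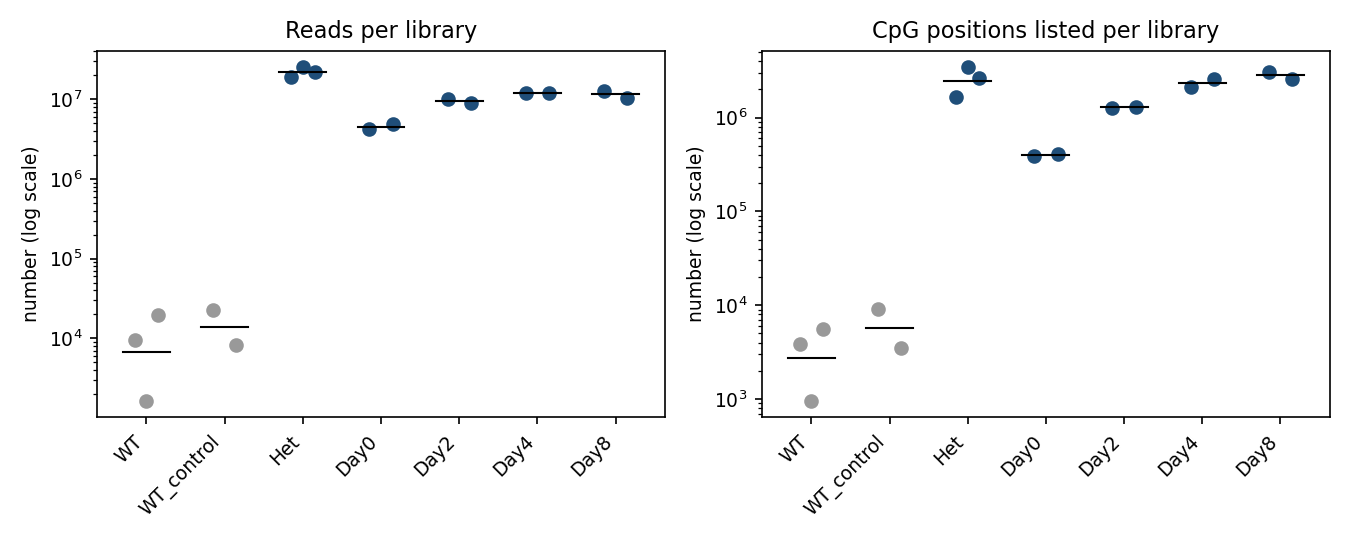
Reads (left) and listed CpG positions (right) per library, on log axes, for each group; points are libraries and bars are geometric means. All Het and day libraries hold at least 4202118 reads, and all wild-type libraries at most 22890; positions on day 0 are 390158 and 407127.

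Listed CpG positions became more numerous over the days of priming. A lower yield of molecules on day 0 could give this as well as fewer labelled sites. Day 0 libraries listed 390158 and 407127 positions, day 2 libraries 1267200 and 1307835, day 4 libraries 2093130 and 2576649, and day 8 libraries 3065096 and 2602884. The number of positions correlated with the day over the 8 libraries, with Pearson r = 0.875 (exact permutation p = 0.00833, adjusted p = 0.0138) and Spearman rho = 0.976 (exact p = 0.000794, adjusted p = 0.00106). Total reads gave r = 0.761 (exact p = 0.0373, adjusted p = 0.0373) and rho = 0.878 (exact p = 0.0103, adjusted p = 0.0103). At 4202118 reads per library, the number of positions still correlated with the day (r = 0.865, exact p = 0.0103, adjusted p = 0.0138). Reads per position correlated inversely with the day (r = -0.937, exact p = 0.00198, adjusted p = 0.00794), from 11.4 ± 0.852 (SD, n = 2) on day 0 to 4.08 ± 0.0453 on day 8. These 4 relations form 1 family, and the smallest exact p possible is 0.000397 for Pearson and 0.000794 for Spearman correlations. Without the 2 day 8 libraries, which lie farthest from the median day, r was 0.979 for positions and 0.950 for reads. For reads, leaving out 1 library raised the exact p above the threshold for 6 of the 8 libraries, namely both of day 0, replicate 2 of day 2, both of day 4 and replicate 1 of day 8, with r between 0.690 and 0.779 and p between 0.0540 and 0.0651.

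Protein-coding gene bodies took most of the reads at every stage. They held 50.9% ± 0.0638 (SD, n = 2) of reads on day 0 and 52.0% ± 0.602 on day 8, against 37.9% of the bases. Sequence within 1 kb of an annotated gene end held 5.96% ± 0.0766 on day 0 and 6.51% ± 0.151 on day 8, against 4.56% of the bases. Sequence outside genes held 41.6% on day 0 and 40.7% on day 8, bodies of lncRNA genes alone 7.54% and 7.34%, and the X chromosome 1.61% and 1.62%. The X chromosome made up 6.28% of the bases, a share that takes no account of how many copies of it a cell holds. No class passed the exact permutation test of its Pearson correlation with the day after Benjamini-Hochberg adjustment over 5 classes. The values were r = 0.828 (adjusted p = 0.0575) near gene ends, -0.771 (0.0665) for lncRNA bodies, 0.678 (0.121) for protein-coding bodies, -0.642 (0.121) outside genes and 0.238 (0.577) for the X chromosome. Without day 8 replicate 2, the first 4 passed, with r = 0.913, -0.792, 0.878 and -0.885, and the X chromosome turned to r = -0.413, against r = 0.664 without day 8 replicate 1. In the Het triplicate, 52.4% ± 0.367 (SD, n = 3) of reads lay in protein-coding bodies and 6.64% ± 0.0937 near gene ends. Reads near gene ends made up 11.0% ± 0.463 (SD, n = 3) in WT and 14.2% ± 0.816 (n = 2) in the wild-type control. Protein-coding bodies held 53.0% ± 2.52 in WT and 54.5% ± 0.391 in the wild-type control, and the X chromosome 1.31% and 1.35%. Shares of protein-coding bodies above, and of the X chromosome below, those of the bases were thus seen without the knock-in too, in libraries of 1640 to 22890 reads.

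Day 0 stood apart in replicate agreement. Across 100 kb windows, which are not independent replicates, the Spearman correlation of replicates was 0.843 on day 0, 0.939 on day 2, 0.967 on day 4 and 0.972 on day 8, and 0.960 to 0.975 within Het. Day 0 libraries correlated with other Het and day libraries at 0.844 to 0.862, and pairs without day 0 at 0.937 to 0.977. Day 0 libraries also listed fewer positions (390158 and 407127, against 1267200 to 3065096 on later days), which by itself can lower agreement. At equal reads the replicate values were 0.842 on day 0 and 0.933 to 0.964 later, but positions stayed unequal. Agreement at equal numbers of positions was not computed. Of the positions in day 0 replicate 1, 5.16% recurred in replicate 2, against 3.44% for independent draws from the 11843512 positions listed in any Het or day library. The same shares were 10.1% against 11.0% on day 2, 18.7% against 21.8% on day 4 and 18.4% against 22.0% on day 8. The set drawn from is the union of these same libraries and not all CpGs of the genome, and a larger set would lower each expected share. Whether days 2, 4 and 8 lay below independent draws is therefore not settled.

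The main comparison set gene bodies on day 8 against day 0, the end points of the transition, with changes relative to the library total. Csmd3, Dlg2 and Nrxn3, very long genes of neuronal adhesion and signalling, rose, while the very long genes Tenm3, Tenm4 and Cacna1c fell (log2 change -0.60, -0.56 and -0.60, adjusted p = 0.0168, 0.0186 and 0.0207; named after their values were seen). Csmd3, a large transmembrane protein with complement-type domains (chromosome 15, 47580638 to 48792558 in mm10), went from 71.2 to 262 TMM-scaled CPM (log2 change 1.88 ± 0.14 SE, adjusted p = 0.00382). Dlg2, a postsynaptic scaffold (chromosome 7, 90476188 to 92449246), rose by 1.06 ± 0.11 (adjusted p = 0.0122), and Nrxn3, a presynaptic adhesion receptor (chromosome 12, 88722701 to 90334935), by 0.87 ± 0.13 (adjusted p = 0.0207). Etv5, an ETS factor of the early post-naive programme, rose by 1.38 ± 0.29 (adjusted p = 0.0416). Among the genes that fell were Cdh5 and Kdr, which encode endothelial cadherin and a VEGF receptor (log2 change -1.21 ± 0.21, adjusted p = 0.0299, and -1.12 ± 0.23, adjusted p = 0.0405). Lama1, a basement membrane laminin, fell by 0.90 (adjusted p = 0.0350), and the imprinted retrotransposon-derived gene Rtl1 fell by 1.29 (adjusted p = 0.0276). In all of these genes both day 8 libraries lay on one side of both day 0 libraries.

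Of 30249 gene bodies tested, 550 rose and 217 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 per day with all 8 libraries in the fit). The fit takes 1 spread per gene from all 8 libraries. Day 0 replicates agreed less than later pairs (Spearman correlation 0.843 against 0.939 to 0.972 in 100 kb windows). The calls thus rest in part on the spread of the later days. Counting each listed position once, 455 rose and 571 fell among 20415 genes, and of the 666 read-based calls tested this way 400 kept their direction and passed. Of the 550 that rose, 239 had no listed position in either day 0 library, as had 3089 of the 30249 tested. DESeq2 called 5294 genes, edgeR with a replicate block 142, and edgeR with only the 4 libraries compared 0, where 4064 genes had an unadjusted p under 0.05. The read-based count depends on which libraries are fitted: 7648 and 7459 genes were called without day 0 replicate 1 or 2, and 0 to 4 without any 1 of the other 6 libraries. Distinct positions gave 272 and 181 calls without day 0 replicate 1 or 2, and 755 to 928 without any 1 of the others.

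**Figure D2:**
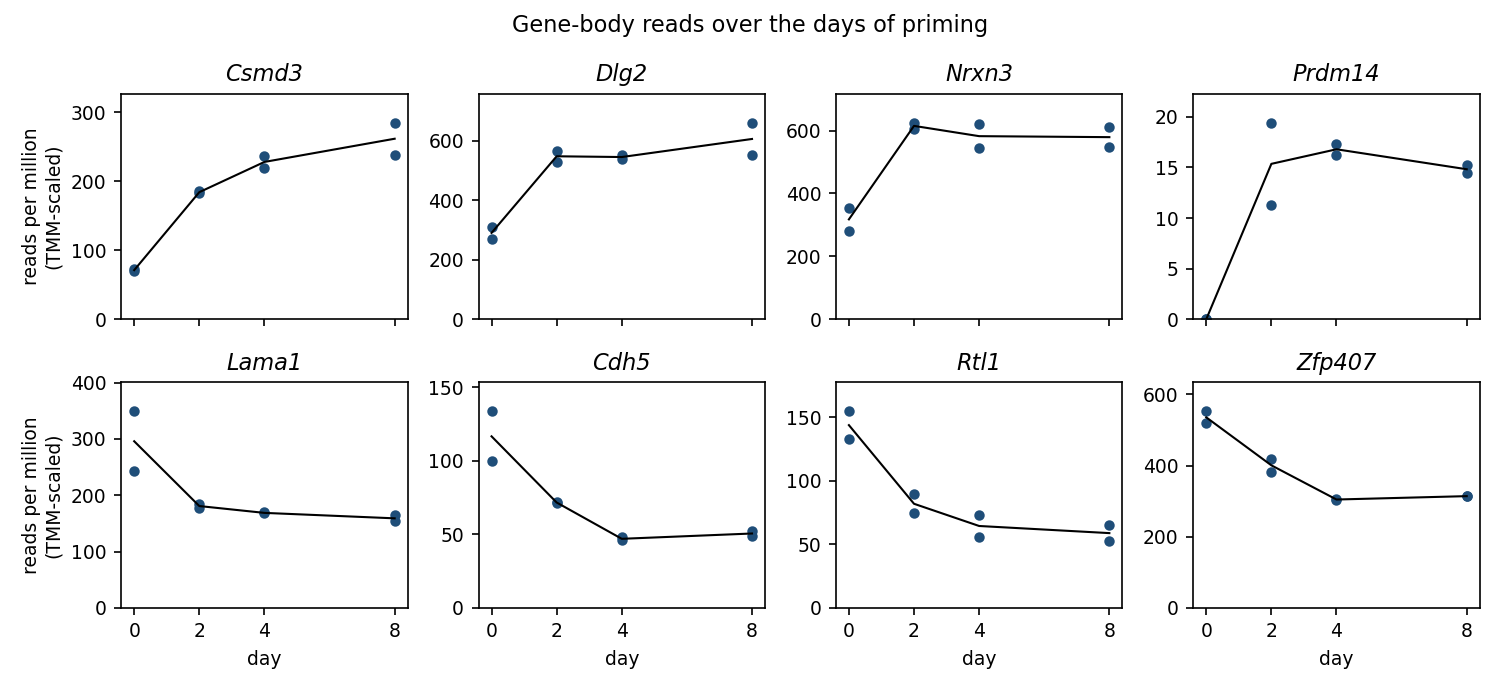
TMM-scaled CPM in the bodies of 8 genes against the day of priming (0, 2, 4, 8); points are the 2 libraries of each day and lines join their means. Csmd3, Dlg2, Nrxn3 and Prdm14 lie higher on day 8 than on day 0, and Lama1, Cdh5, Rtl1 and Zfp407 lower; Csmd3 means are 71.2 on day 0 and 262 on day 8.

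The rule fixed before the data were examined ranks fitted changes, and the 8 genes it named as higher all lacked a listed position on day 0, so their order and size are not determined beyond lower bounds. They were the p53-linked lncRNA Trp53cor1, its neighbour Cdkn1a (the cell cycle inhibitor p21), the paraspeckle lncRNA Neat1, the 14-3-3 protein gene Ywhaz, the mitochondrial assembly factor Cox19, and Gm4117, Gm14273 and LOC115486328. Bounds are set against a floor of 3 positions over the day 0 group, relative to all positions listed. They cover counting error of the day 0 count only, and none of the later count. Trp53cor1 (chromosome 17, 29057474 to 29079126) was at least 6.19-fold higher on day 8, with 132 positions, and Neat1 (chromosome 19, 5824708 to 5845480) at least 5.39-fold higher, with 115. Gm4117 was at least 3.80-fold, Ywhaz 3.47-fold, LOC115486328 3.28-fold, Cdkn1a 3.24-fold, Gm14273 3.05-fold and Cox19 2.53-fold higher. Their edgeR adjusted p ran from 0.0112 for Trp53cor1 to 0.0207 for Cox19. The largest decreases were in Smn1, a factor of snRNP assembly (-2.79 ± 0.60, adjusted p = 0.0453), and in 7 predicted genes, from Gm30618 (-3.15 ± 0.53, adjusted p = 0.0276) to Gm41347 (-2.30 ± 0.43, adjusted p = 0.0354). The others were Gm52723, Gm19951, Gm15478, Gm52359 and Gm10636. Counted by distinct positions, Gm52723 did not pass (-1.38, adjusted p = 0.112).

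The gene lists were fixed beforehand and tested as groups. Among 25 long genes of cell adhesion, 7 rose and 0 fell (15 rose adjusted over the list alone). They included Csmd3, Dlg2, the potassium channel subunit Dpp10 (1.10 ± 0.16, adjusted p = 0.0207) and Cntnap2 of the neurexin family (0.65 ± 0.11, adjusted p = 0.0273). Counted by distinct positions, 16 of the 25 rose (18 adjusted over the list alone), and the list's median log2 change was 0.54. The list ranked higher than other genes by camera with a preset correlation (adjusted p = 1.17e-06), with adjusted p = 0.213 with an estimated correlation. Of 27 clustered protocadherins, 4 rose and 0 fell (9 rose adjusted over the list alone), all of the gamma cluster on chromosome 18. They included Pcdhga2 (0.90 ± 0.17, adjusted p = 0.0364) and Pcdhgb7 (1.43 ± 0.22, adjusted p = 0.0229), whose gene bodies share their 3' part and hence reads, so these are not separate observations (camera adjusted p = 6.83e-05, adjusted p = 0.104 with an estimated correlation).

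Among 20 naive pluripotency genes, 3 rose and 0 fell (5 rose adjusted over the list alone). Prdm14 and Tbx3, transcriptional regulators of the naive state, had no position on day 0 and were at least 2.67-fold and 1.78-fold higher on day 8 (adjusted p = 0.0207 and 0.0350), though Tbx3 did not pass by distinct positions (adjusted p = 0.0542). Klf5, named after its values were seen, had 1 position on day 0 (adjusted p = 0.0413). The list was called by camera (adjusted p = 0.000492), with adjusted p = 0.104 with an estimated correlation. Housekeeping and ribosomal genes (1 of 28 rose, Eef2) and vomeronasal receptors (1 of 106 passed, Vmn2r65) were called higher by camera too. Both lists had adjusted p = 0.0109, and adjusted p = 0.104 with an estimated correlation. Vmn2r65 had 0 positions on day 0 and 29 on day 8, 1.36-fold against the floor with no counting error taken on the 29. Eef2 had 1 position on day 0 and did not pass by distinct positions (adjusted p = 0.0745). Adjusted over the list alone, 1 housekeeping gene and 0 vomeronasal receptors rose. Neither list passed with distinct positions (adjusted p = 0.140 and 0.921), nor without day 0 replicate 1 (0.215 and 0.335) or 2 (0.172 and 0.244). None of the 19 lists passed with an estimated correlation.

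The other 14 lists were not called, with camera adjusted p from 0.0958 to 0.988. Genes with germline-methylated promoters ranked lower on day 2 (adjusted p = 0.0380, adjusted p = 0.317 with an estimated correlation), and on day 8 only without day 0 replicate 2 (adjusted p = 0.0400). Of 46 imprinted genes, 3 fell and 1 rose (4 each adjusted over the list alone). Rtl1, Trappc9 (-0.50 ± 0.10, adjusted p = 0.0368) and Igf2r, the mannose 6-phosphate receptor (-0.85 ± 0.17, adjusted p = 0.0416), fell. Blcap, without a position on day 0, rose (adjusted p = 0.0462), though not by distinct positions (adjusted p = 0.0748). By distinct positions Peg3 and Peg13 fell as well (edgeR adjusted p = 0.0137 and 0.00630). Peg13 lies within Trappc9, so its positions count for both and it is not a separate observation. Of 20 endoderm markers, 3 fell: Lama1, Lamb1 (-0.96 ± 0.22, adjusted p = 0.0490) and Col4a2 (-0.61 ± 0.13, adjusted p = 0.0463), all basement membrane components (3 adjusted over the list alone). Of 18 mesoderm markers, Cdh5 and Kdr fell (2 fell and 1 rose adjusted over the list alone). Of 19 ectoderm and neural markers, Dlg2, Nrxn3 and the RNA-binding protein gene Elavl3 (1.88 ± 0.32, adjusted p = 0.0276) rose (8 adjusted over the list alone), Elavl3 only in reads (adjusted p = 0.115 by distinct positions). That list shares Dlg2, Nrxn3, Ctnna2 and Lsamp with the long genes, and it passed camera with distinct positions (adjusted p = 1.51e-06, and adjusted p = 0.171 with an estimated correlation). Blcap, Igf2r, Lamb1, Elavl3, Peg3, Peg13, Dpp10 and Cntnap2 were named after their values were seen.

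Among the remaining lists, Etv5 was the 1 of 19 formative and primed genes that rose (1 adjusted over the list alone), and the focal adhesion gene Tgfb1i1 the 1 of 20 fibroblast markers (2 adjusted over the list alone). Tgfb1i1 had 1 position on day 0 and did not pass by distinct positions (adjusted p = 0.167). By distinct positions the only fibroblast marker called was Ddr2, named after its values were seen, which fell (-0.57 ± 0.18, edgeR adjusted p = 0.0334). Of 379 zinc finger genes, 6 rose and 5 fell (10 and 7 adjusted over the list alone), and 6 rose and 14 fell of 289 by distinct positions, among them Zfp710 (1.67 ± 0.20, adjusted p = 0.0153) and Zfp407 (-0.77 ± 0.10, adjusted p = 0.0172). Of 844 X-linked genes, 10 rose and 0 fell (5 adjusted over the list alone), among them Frmpd4 (adjusted p = 0.0193) and Arhgap6 (1.44 ± 0.23, adjusted p = 0.0249). Of 348 olfactory receptors, Olfr282 and Olfr558 passed with 0 positions on day 0 (0 adjusted over the list alone). Against the floor of 3 positions, Olfr282 came to 1.03-fold and Olfr558 to 0.844-fold. No counting error was taken on their 22 and 18 day 8 positions, so no rise is bounded for either. In the edgeR test on reads no member was called among 45 Hox and Polycomb target genes, 31 genes with germline-methylated promoters, 19 genes of the DNA methylation machinery, 17 trophoblast markers or 8 genes of the 2-cell-like state. Adjusted over the list alone, 2 germline genes rose and 3 fell, 2 trophoblast markers rose, and the other 3 lists had 0. By distinct positions the germline genes Tdrd1 and Tuba3a fell (adjusted p = 0.0101 and 0.0241) and the trophoblast marker Gata2 rose (adjusted p = 0.0311), named after their values were seen.

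**Figure D3:**
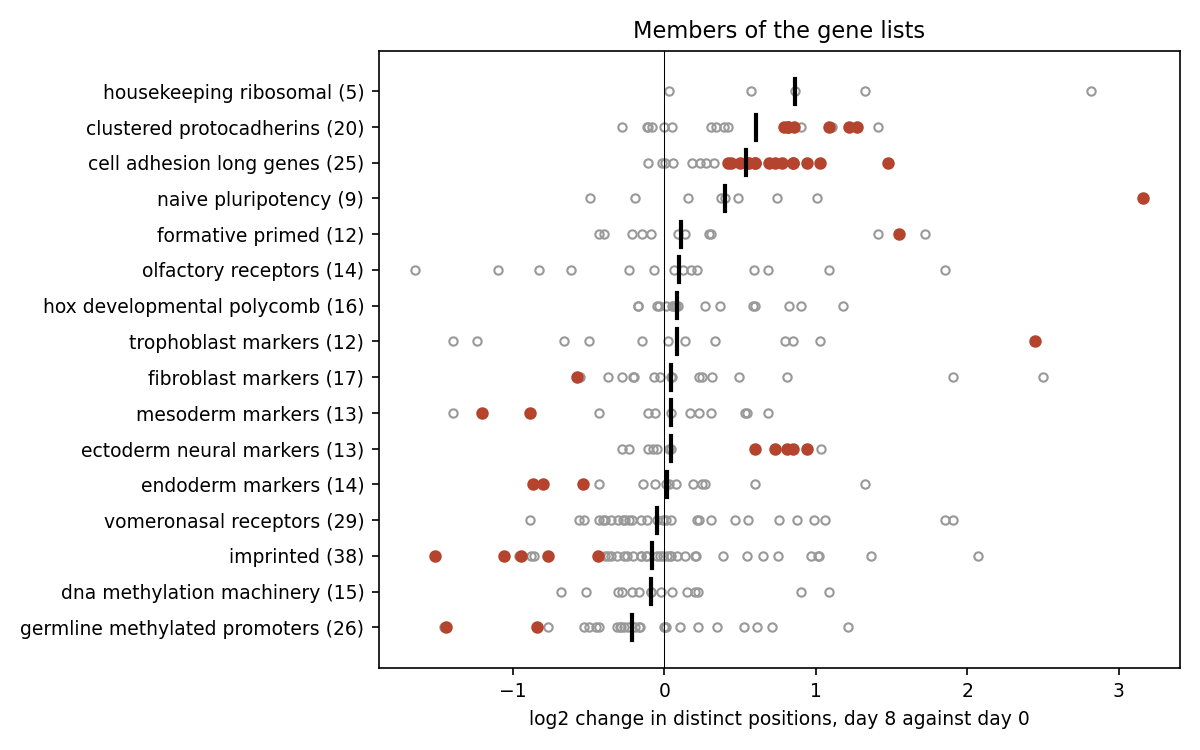
Log2 change in distinct positions, day 8 against day 0, for list members with at least 1 position on day 0 (number in brackets); filled points passed the edgeR test and bars are medians. The 25 long cell adhesion genes have a median of 0.54 with 16 filled points. The 38 imprinted genes have a median of -0.08 with 5 filled points, all below 0, among them Trappc9 and Peg13, which share positions.

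The enzymes of methylation and the pluripotency genes fixed for reporting mostly did not pass the test. Dnmt1 itself had 97.9 CPM on day 0 and 118 on day 8 (log2 change 0.27 ± 0.16, edgeR adjusted p = 0.347). Values were -0.07 ± 0.16 for Dnmt3a (adjusted p = 0.863), -0.07 ± 0.40 for Dnmt3b (0.946), 0.27 ± 0.65 for Dnmt3l (0.859) and 0.07 ± 0.20 for Tet1 (0.892). Esrrb, an orphan receptor of naive cells, had 0.40 ± 0.15 (adjusted p = 0.152), and the primed-state gene Fgf5 -0.01 ± 0.61 (0.997). Nanog had 0 positions on day 0 and 19 on day 8 (adjusted p = 0.109), Klf4 had 1 and 10 (0.280), and Otx2 2 and 20 (0.650). Relative to all listed positions, the ratio of day 8 to day 0 was 1.41 for both Klf4 and Otx2. Their exact 95% counting intervals began at 0.200 and 0.342, so no change was detectable at this depth.

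By day 2, Trp53cor1, Neat1, Gm4117 and Cox19 already exceeded day 0, by at least 4.13-fold, 3.51-fold, 2.68-fold and 2.37-fold in positions against the same floor. Gm30400 (-2.59 ± 0.49), Gm52359 (-2.58 ± 0.47), Gm37292 (-2.49 ± 0.48) and Gm46240 (-2.26 ± 0.41) had the largest decreases, with edgeR adjusted p of 0.0444 to 0.0460. In all, 223 gene bodies rose and 50 fell on day 2, and 91 and 143 by distinct positions. Without day 0 replicate 1 or 2 the test called 7165 and 7093 genes, and 0 without any 1 of the other 6 libraries, where 4642 to 5080 genes had an unadjusted p under 0.05. DESeq2 on all 8 libraries called 4817. The edgeR test with a replicate block called 2 higher and 0 lower, so no decrease kept its call there. Distinct positions gave 51 and 33 calls without day 0 replicate 1 or 2, and 129 and 91 without day 2 replicate 1 or 2.

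On day 4, Trp53cor1, Neat1, Ywhaz and Cdkn1a were at least 5.41-fold, 5.01-fold, 3.70-fold and 3.30-fold higher than on day 0. Nutm2 (-3.50 ± 0.71), 4933406G16Rik (-2.81 ± 0.61), the kinetochore gene Spc25 (-2.71 ± 0.59) and Gm52359 (-2.53 ± 0.46) had the largest decreases, with edgeR adjusted p of 0.0336 to 0.0462. The test called 632 gene bodies higher and 254 lower, and distinct positions 379 and 528. Without day 0 replicate 1 or 2 it called 7728 and 7540, and without any 1 of the others 0 to 7. Distinct positions gave 256 and 180 calls without day 0 replicate 1 or 2, and 548 without day 4 replicate 2. All 3 comparisons share the day 0 libraries, so part of any likeness between them may come from those libraries.

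Near gene ends, 1 of 28895 genes passed on day 8 and 0 on days 2 and 4. It was AY036118, a lncRNA record on chromosome 17 (39848112 to 39898385), which rose from 586 and 360 to 3041 and 2602 CPM (log2 change 2.58 ± 0.19, edgeR adjusted p = 0.000442). Its body rose in reads (adjusted p = 0.0194) and had -0.64 in distinct positions (adjusted p = 0.139), so the rise in the body was in reads and not in positions. Reads of near-identical copies are not told apart, so whether these reads came from this locus is not settled. Unadjusted p was under 0.05 for 7524 genes on day 8, 7269 on day 2 and 7563 on day 4, and DESeq2 called 4647, 4553 and 4463. Of its day 8 calls 4562 were higher and 85 lower, and the median log2 change over all gene ends was 1.22 with TMM and 0.66 with library totals, so this comparison is not centred on 0. By distinct positions 5 genes passed on day 8, named after their values were seen: Mylk2 rose, and Tmem267, its overlapping neighbour 3110070M22Rik, Gm33102 and Rhox4g fell. Without day 0 replicate 1 or 2 the day 8 test called 3570 and 1910 genes. On simulated day 8 libraries it recovered 0% of 100 genes changed 4-fold, so counts near gene ends say little.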

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

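Settings that combine distinct positions with thinning, DESeq2, 4 libraries or left-out libraries, and counts of calls within 500 bases of gene ends, were chosen after seeing the data. The excess of Het over WT kept its direction in every setting run, 1600-fold to 5549-fold with 1 library left out. The excess of the day libraries over the control ranged from 383-fold to 1072-fold with 1 library left out, where the smallest possible exact p rose to 0.111 without a control library. Over the days, r for reads ranged from 0.690 to 0.821 with 1 library left out. The feature classes ranged, with 1 library left out, from 0.565 to 0.878 for protein-coding bodies, -0.839 to -0.708 for lncRNA bodies, -0.885 to -0.502 outside genes, 0.768 to 0.913 near gene ends and -0.413 to 0.664 for the X chromosome. Over the replicate pairs of the day libraries alone, without the Het pairs, the median correlation of 0.953 was 0.718 in 10 kb windows.

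Gene bodies called on days 2, 4 and 8 numbered 273, 886 and 767. DESeq2 called 4817, 5452 and 5294, and thinning to equal reads 181, 538 and 565. Without a filter on low counts 517 were called on day 2. Fits of only the 4 libraries compared called 0, 0 and 0, with 2410, 4015 and 4064 genes at an unadjusted p under 0.05. Fewer libraries leave fewer degrees of freedom, and such a fit takes no spread from the other later days. Which of these lowered the counts was not tested. Leaving out 1 library gave 0 to 7165, 0 to 7728 and 0 to 7648 calls. Distinct positions called 234, 907 and 1026, and with 1 library left out 33 to 230, 180 to 849 and 181 to 928. The counts over 1.5 times from the full fit were 51 and 33 without day 0 replicate 1 or 2 and 129 and 91 without day 2 replicate 1 or 2 for day 2, 256 and 180 without day 0 replicate 1 or 2 and 548 without day 4 replicate 2 for day 4, and 272 and 181 without day 0 replicate 1 or 2 for day 8. Thinned to equal numbers of positions they called 71, 273 and 311, with fewer genes tested. With DESeq2, distinct positions called 113, 448 and 509, and with only the 4 libraries 146, 777 and 430. Near gene ends the count of 1 became 4647 with DESeq2, 5 with distinct positions, 0 with only the 4 libraries (3812 at an unadjusted p under 0.05), and 1 to 3570 with 1 library left out. Where no cause is named, the cause was not tested.

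Of the 19 lists, 5 were called, and 0 with an estimated correlation, for reads or for distinct positions; leaving out 1 library of day 0 or day 8 gave 3 to 5. List tests were not run without a day 2 or day 4 library. With an estimated correlation the adjusted p was 0.104 for naive, housekeeping, protocadherin and vomeronasal genes and 0.213 for long adhesion genes. With distinct positions and an estimated correlation it was 0.171 for naive and long adhesion genes, 0.312 for housekeeping and protocadherin genes and 0.916 for vomeronasal receptors. With distinct positions alone, housekeeping genes had 0.140 and vomeronasal receptors 0.921. With 1 library of day 0 or day 8 left out, adjusted p ranged from 0.00221 to 0.215 for housekeeping, 0.00904 to 0.335 for vomeronasal, 0.000156 to 0.0396 for naive, 9.27e-05 to 0.00964 for protocadherin and 1.47e-09 to 0.00105 for long adhesion genes. Of 39 named genes called on day 8, 39 kept their call with DESeq2, 38 with library totals and 36 with thinned reads, and 32 of the 36 tested by distinct positions did. With only the 4 libraries compared, 0 of the 39 kept the call. A fit without 1 library leaves 1 library in its group, whose spread then comes from the other days. Calls kept or lost in such fits therefore say little about these genes. None of the 39 turned direction. AY036118, named for its ends and not among the 39, did: its body had -0.64 by distinct positions.

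Replicate numbers did not pair the day libraries: differences between replicates 1 and 2 correlated between days at -0.00994 to 0.0162. With the replicate block, the gene-body counts were 2, 119 and 142, 18 of the 39 named genes kept the call, and 5 lists stayed called. An exact permutation test within the blocks gave p = 0.25 for Het against WT and p = 0.04 for the day libraries against the control, each the smallest such a test can give.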

Other observations

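The genes in this part were chosen after seeing the data, as were the tests of the number of positions; the tests of the long genes and of genes without day 0 positions were set down before their results were seen. Counted by distinct positions, genes beyond those named by the rule changed on day 8, and long neuronal genes were among both those that rose and those that fell. Foxp2, a forkhead factor of speech-related circuits, rose by 1.58 ± 0.24 on the log2 scale (edgeR adjusted p = 2.91e-08), and the potassium channel genes Kcnh7 and Kcnd2 by 1.64 ± 0.25 and 1.43 ± 0.22 (4.09e-08 and 9.37e-08). The adhesion genes Mdga2 and Cadm2 rose by 1.21 ± 0.19 and 1.07 ± 0.17 (1.45e-07 and 4.41e-07). Other genes fell: the large tumour suppressor gene Wwox (-0.67 ± 0.06, adjusted p = 2.32e-26), the muscle gene Ttn (-0.92 ± 0.09, 1.08e-20), the developmental factors Sox5 (-0.62 ± 0.07, 7.44e-16) and Foxp1 (-0.60 ± 0.08, 1.08e-11), and Prkce, Tenm3, Tenm4 and the calcium channel gene Cacna1c. All of these passed with reads as well. Sfi1 had the smallest adjusted p (-1.93 ± 0.14, 7.43e-40), with a smaller change in reads (-0.64 ± 0.09). It held 198 day 0 positions in 71.5 kb, against 958 in 913 kb for Wwox, and reads of near-identical copies are not told apart. With a fitted spread close to counting error, such small p-values reflect the number of positions in 2 libraries per day. They do not measure the spread between further cultures.

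Among 232 tested genes of 500 kb or more, 61 rose and 35 fell by distinct positions, against 52 and 105 of 819 genes from 200 to 500 kb and 64 and 104 of 1643 genes from 100 to 200 kb. The difference between these classes was not tested.

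Over the days of priming, more CpG positions were listed. Unequal sequencing depth is argued against, since at equal reads the lowest day 8 library still listed 4.90 times the positions of the highest day 0 library. Reads per position at equal reads, 5.19 times as many on day 0 as on day 8, only restate the difference in positions. Fewer labelled sites and a lower yield of molecules could both give it, and they cannot be told apart without a spike-in or molecular identifiers. More DNMT1 activity after withdrawal of the inhibitors stays open as a hypothesis, which these counts do not test.

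Of the 25 long adhesion genes, 7 rose in reads and 16 by distinct positions, and the list did not pass with an estimated correlation (adjusted p = 0.213 and 0.171). Whether length alone gives the list's shift is not settled. The list's median log2 change of 0.54 lay at the 99.97th percentile of 10000 random lists drawn from genes nearest in length, whose median was 0.15. These random lists were shorter, however (median 1106 against 1485 kb). By distinct positions, the median change of tested genes was -0.044 from 200 to 500 kb and 0.15 at 500 kb or more. Members of the list were also correlated (estimated 0.50), which random draws of genes do not reproduce. Drawn to match also on listed positions per kb, random lists were shorter still (818 kb), with a median of 0.40, and the list lay at the 94.4th percentile. The shift may thus be one of long genes with few listed positions per kb in general. Few listed positions can mean little label or few CpGs, which were not told apart. A shift of the whole neighbourhood is less likely from the sequence outside genes within 1 gene length on each side, whose median log2 ratio was 0.0580 against 0.60 in the gene bodies, with 16 of 25 flanks and 24 of 25 bodies above 0; flanks can hold far more positions than bodies (356 against 46 on day 0 for Csmd3), so they are no matched control and this stays open. A hypothesis that stays open is that DNMT1 label accumulates during priming within the bodies of long genes with few listed positions per kb, and less in the sequence beside them. Counts per reference CpG with molecular identifiers, in further cultures, would test it.

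Genes such as Trp53cor1, Neat1 and Prdm14 had no position on day 0. Sparse sampling is argued against as the whole cause: of 17698 genes with at least 50 positions in the Het triplicate, 88 had none on day 0, 3.38 times the 26 in the highest of 60 draws from later pairs thinned to the same numbers. The Het libraries used for this filter correlated less with day 0 than with later days, which may raise the ratio. Genes without day 0 positions held 1.24 times the positions per kb of genes with as many Het positions (8.49 against 6.86). With the number of positions matched, gene length alone can give this ratio, and it counts listed positions, not CpGs. Whether CpG-dense sequence was lost from the day 0 libraries was therefore not measured, and such loss cannot be told apart from absent labelling. That these loci carried little DNMT1 label in naive cells remains a hypothesis, which labelled CpG-dense DNA spiked into day 0 samples before enrichment would test.

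Of the positions in the 3 WT libraries, 39.2% to 40.3% were also listed in the Het triplicate, and 37.9% and 38.6% of those in the wild-type control, against 44.2% and 43.8% for the day 8 libraries.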
